A study of Homo sapiens with 4 samples.

How the data were processed

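RNA from A375 and SK-MEL-28 cells, transfected with a negative control siRNA or a ZIC5 siRNA and collected after 48 h, was hybridised to 4 HG-U133 Plus 2.0 arrays, 1 per group, from 100 ng of total RNA labelled as biotinylated cRNA, per the labels' protocols. The authors deposited 1 intensity per probe set and array, made with RMA in Affymetrix Expression Console per the submitters' processing notes, with versions not given in the sources used here. The deposited intensity values were on a linear scale, as their range from 2.8 to 22531 shows, and log2 was taken here. No detection calls were used, and with no count of reads or molecules the precision is limited by the number of arrays. Samples were grouped by the labels alone.

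Probe sets were named through the platform annotation of August 2016 given with the data. Of 54613 probe sets, 41091 named 1 gene, 1801 named several and were not used for genes, and 11721 had no gene name in that table and entered only a count in the closing section. Symbols were checked through entrez IDs against the RefSeq table of assembly GRCh38.p14: 41037 probe sets matched, 54 did not, and 0 symbols changed. No coordinates are given, as no genome build is named by the files. Each gene was represented by the probe set with the highest mean over the 4 arrays, and a different sign among its probe sets at the level minimum is given in the text for siRNA differences of at least 2-fold and for genes that passed a test. Sizes can differ between probe sets of a gene even where the signs agree, and this is given only for some genes. Genes with a mean log2 intensity of at least 5 (intensity 32) were analysed, 13794 of 19775. XIST and Y-linked genes were left out of named genes and lists.

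Within a line, genes were described by a size rule, a log2 difference of at least 1 (2-fold), with no p-value because each group held 1 array. Overlap of the lines was set against the product of the list sizes over the genes analysed and against simulated arrays with no changed gene, drawn with 1 spread per gene in both lines from the limma prior. The lines have separate control arrays, so no control is shared. The siRNA effect over both lines and the line difference came from 1 additive fit (lmFit and eBayes with trend, limma 3.58.1 in R 4.3.3) with Benjamini-Hochberg adjustment at 0.05 and 1 residual degree of freedom per gene. Its SE blends the disagreement of the lines for a gene with a spread pooled over genes by eBayes, with 2.85 prior degrees of freedom. The SE of a gene can therefore be smaller or larger than the disagreement of the lines for that gene. An interaction could not be fitted. The labels do not say whether any samples came from separate cultures of a group, so p-values measure only the spread between these arrays.

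A set of 40 gene lists was fixed before the data were examined, from general knowledge of pathways, melanoma biology and other cell types, and a few members were chosen with the study's interest in PDGFD, PTK2, STAT3 and CDH1 known. The lists held 702 members, of which 589 were measured. Older symbols were updated, and members under the level minimum, without a probe set of their own or left out of the data are not analysed here. Each list's median was placed as a percentile among 10000 random lists of the same size drawn from 20 bins of mean level, which describes these arrays and is no test of the conditions. Limma p-values were also adjusted over each list alone, and no adjustment was made across the lists. A further 4 lists were added after the data were seen and appear only in the closing section.

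The rule for named genes, also fixed beforehand, took ZIC5, the ZIC and PDGF lists with CDH1, PTK2 and STAT3, the 10 highest and 10 lowest differences in each line, the 10 and 10 ranked by the smaller change in both lines, the 10 and 10 with the lowest limma adjusted p, the 10 and 10 with the greatest line difference, and up to 4 members of each other list with the greatest mean change. Many genes shared the lowest limma adjusted p, so the 10 and 10 for it were taken in order of unadjusted p. List members named beyond this rule were chosen after their values were seen: those that passed, or did not pass, over the ATF4, MAPK and integrin lists. The fit was tested on simulated data: with 200 genes among 13794 changed by 1 log2 unit it called 0% over all genes but 92.7% of members of changed lists of 18 genes adjusted over the list alone, and 4% of 200 unchanged lists held a call when no gene was changed. The percentile step was run on lists of 18 genes drawn at random after the A375 differences were shuffled over genes. Of these lists 5.5% fell outside the central 95% of random lists, and 97% did after a shift of 0.5. The first share follows from the random draw. The shuffle removes any trend on level and any variation of genes together, so this checks the calculation only.

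The alternatives set beforehand were no level filter, a minimum of 7, values under 5 set to 5, loess of each line's difference on mean level with span 0.4, quantile normalization again, the mean of all probe sets of a gene, size rules of 1.5-fold and 3-fold, Spearman correlation, eBayes without trend or with robust estimation, no block, an adjusted p under 0.1, and an added 2-fold minimum. Intervals in the closing section are 95% bootstrap intervals over genes from 1000 resamples or ranges of random lists.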

Results

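Gene expression was measured on 4 whole-transcriptome arrays (HG-U133 Plus 2.0), 1 for each combination of 2 human melanoma cell lines and 2 transfections. A375 and SK-MEL-28, established lines that both carry an activating BRAF mutation, had received either a negative control siRNA or an siRNA against ZIC5, a zinc-finger transcription factor of the ZIC family, 48 h before RNA was collected. The table held 54613 probe sets per array, and 41091 of them named a single gene, which gave 19775 genes. The median intensity was 39.4 on the A375 control array, 38.8 on the A375 ZIC5 siRNA array, 38.8 on the SK-MEL-28 control array and 38.4 on the SK-MEL-28 ZIC5 siRNA array. Differences are log2 intensity with ZIC5 siRNA minus that with control siRNA in the same line, and counts cover the 13794 genes whose mean log2 intensity over the 4 arrays was at least 5. No group had a replicate array, so a difference within a line has no replicate check. The number of arrays limits the precision throughout.

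The targeted gene was read first. ZIC5 had 1 probe set, and its intensity was 16.8 with control siRNA and 14.1 with ZIC5 siRNA in A375, a difference of -0.25. In SK-MEL-28 the ZIC5 intensities were 21.4 and 15.5, a difference of -0.47. The probe set lay between percentiles 25.7 and 34.5 of all probe sets on these arrays and under the level minimum, so its intensities were near the low end of the scale, and with intensities under 32 set to 32 the difference was 0 in both lines. Neither the size nor the direction of the knockdown can be read from these arrays, and they give no check on the labels. Among other ZIC genes, ZIC2 differed by -1.01 in A375 and -0.28 in SK-MEL-28, ZIC1 by -0.41 and 0.23, and ZIC4, also under the level minimum, by -0.20 and -0.27.

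**Figure D1:**
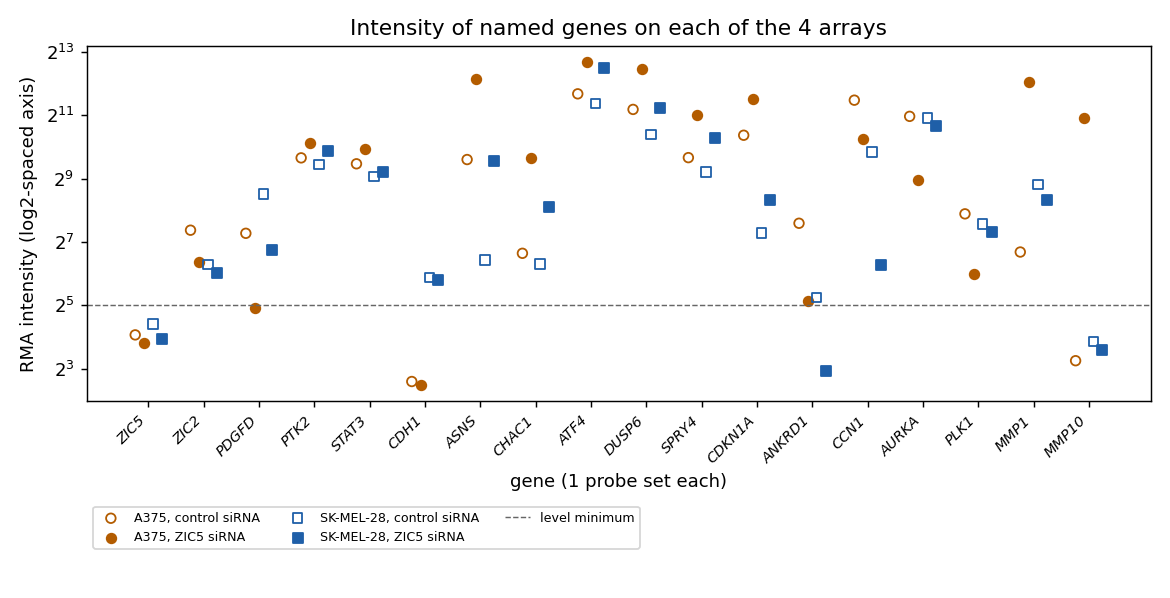
RMA intensity of 18 named genes on each of the 4 arrays, on a log2-spaced axis, with 1 point per array, open symbols for control siRNA and filled symbols for ZIC5 siRNA. The dashed line is the level minimum (intensity 32); the ZIC5 points lie below it on all 4 arrays, and PDGFD and ASNS differ between transfections in both lines.

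The study's interest in ZIC5 in melanoma has centred on the growth factor PDGFD, on focal adhesion kinase (PTK2) and STAT3, and on E-cadherin (CDH1). PDGFD intensity was 155 with control siRNA and 30.2 with ZIC5 siRNA in A375, and 366 and 107 in SK-MEL-28, so it was 5.14-fold lower and 3.44-fold lower. Its mean difference over the lines was -2.07 (SE 0.22 from the limma fit, 2 lines), with a limma adjusted p of 0.268 over all genes and 0.00551 adjusted over the list alone. Of the 6 measured PDGF ligands and receptors, PDGFD alone passed over the list alone, and that list was drawn up with the study's interest in PDGFD known, so its count is not independent evidence. PDGFC differed by 0.02 in A375 and -0.68 in SK-MEL-28 (-0.09 with intensities under 32 set to 32), PDGFRL by -0.20 and -0.42, PDGFB by -0.01 and -0.28, PDGFA by -0.21 and -0.04, and PDGFRB by -0.10 and 0.01. The list median was -0.15 in A375 and -0.35 in SK-MEL-28. PTK2 transcript was higher by 0.47 and 0.42, and 3 of its 4 probe sets at the level minimum, the only ones counted for signs, had that sign in A375, while STAT3 transcript was higher by 0.48 and 0.16. CDH1 had intensities of 6.0 and 5.6 in A375 and of 59.2 and 56.0 in SK-MEL-28, differences of -0.10 and -0.08 on a gene under the level minimum.

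The A375 comparison asked which transcripts differ when ZIC5 is targeted in that line. The 2 largest positive differences were in matrix metalloproteases: MMP10 intensity was 9.5 with control siRNA and 1943 with ZIC5 siRNA, and MMP1 intensity was 103 and 4284, a 41.6-fold difference. The MMP10 difference of 7.67 starts from a value near the bottom of the scale, and it was 5.92 when intensities under 32 were set to 32. The early growth response factor EGR1 was 22.3-fold and the secreted glycoprotein STC1 13.1-fold higher, and the sestrins SESN3 and SESN2 were higher by 3.67 and 3.32. ASMTL was higher by 4.45, the receptor LPAR6 by 3.53, the cysteine-forming enzyme CTH by 3.43 and the neuroendocrine chaperone SCG5 by 3.26. The cytokine IL11 was 12.1-fold lower, the matrix proteoglycan LUM 10.8-fold lower (5.05-fold with intensities under 32 set to 32), TMEM255A 9.36-fold lower (2.23-fold set so) and the matrix glycoprotein EFEMP1 7.53-fold lower. The other IL11 probe set at the level minimum differed by -1.38. The transcription factor PLAGL1 was lower by a difference of -2.64, ANKRD1 of -2.45, the RNA COSMOC of -2.42, the integrin subunit ITGA4 of -2.38 and TMEM45A of -2.37. FAM20C had -2.57 on its highest probe set, but only 1 of its 4 probe sets had that sign. In all, 537 genes were at least 2-fold higher and 697 at least 2-fold lower, 8.95% of genes. The SD of the differences over genes was 0.60, and the median SD between probe sets of a gene was 0.25.

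Cell division genes stood at the low end of the A375 response. Of 26 mitotic genes measured, 24 were at least 2-fold lower, with a list median of -1.38, which was below all 10000 random lists matched on level. AURKA differed by -2.02, PLK1 by -1.91, ANLN by -1.71 and AURKB by -1.65. Genes of the G1/S transition and DNA replication had a median of -0.71 over 26 genes, also below all random lists, with GINS1 at -2.01 and CDC6 at -1.28, and DNA repair genes had a median of -0.55 (percentile 0.1). Cholesterol synthesis genes had a median of -0.62 (percentile 0.03), with MSMO1 at -1.27 and the regulator SREBF2 at -1.13, where 2 of its 3 probe sets had that sign. At the high end, ATF4 stress and amino acid genes had a median of 1.34 over 18 genes, 13 of them at least 2-fold higher, and lysosome and autophagy genes had a median of 0.72 over 18 genes, with MAP1LC3B at 1.58, ULK1 at 1.34 and GABARAPL1 at 1.13. Both medians were above all random lists. NF-kB targets and cytokines had a median of 0.72 (percentile 99.99), with IL24 at 1.70 and NFKBIZ at 1.35 but CCL20 at -2.05 (-1.64 with intensities under 32 set to 32). Among p53 targets the median was 0.60 (percentile 99.96), with the stress cytokine GDF15 at 3.23 and TP53INP1 at 1.35 on 1 of its 2 probe sets but -0.31 on the other, and among apoptosis regulators it was 0.33 (percentile 99.13), with BCL2A1 at 1.70 and BID at -1.11.

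The same comparison in SK-MEL-28 gave fewer genes past the size rule. The amino acid enzyme ASNS, which makes asparagine, had the largest positive difference: its intensity was 86.0 with control siRNA and 760 with ZIC5 siRNA, 8.83-fold higher. RAB11FIP4 was higher by 2.06, SCML4 by 1.99, the sialyltransferase ST8SIA4 by 1.97, AMMECR1 by 1.91, SESN3 by 1.87, LBH by 1.85, EGR3 by 1.82, the glutathione-degrading enzyme CHAC1 by 1.80 and the lipid enzyme GPAM by 1.69. The matricellular protein CCN1 was 11.8-fold lower, from 920 to 78.2, and the chemokines CXCL8 and CXCL1 were 8.04-fold and 5.31-fold lower. The Wnt antagonist DKK1 was 7.02-fold lower, TMEM255A 6.82-fold lower, and the myosin kinase MYLK 6.65-fold lower. The translation termination factor GSPT1 differed by -2.59, and KRCC1, ANKRD1 and the mitochondrial scaffold PHB2 differed by -2.38, -2.33 and -2.31. With intensities under 32 set to 32, the differences of ST8SIA4 and ANKRD1 became 0.52 and -0.25, and 3 of 4 ST8SIA4 probe sets had its sign. In all, 107 genes were at least 2-fold higher and 292 at least 2-fold lower, 2.89% of genes. The SD of the differences over genes was 0.39, and the median SD between probe sets of a gene was 0.15.

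In SK-MEL-28 the ATF4 list was again the highest, with a median of 0.90 above all random lists and 9 of 18 genes at least 2-fold higher. The G1/S and DNA replication list had a median of 0.35, above all random lists, with 23 of 26 genes higher and E2F2 at 1.26, where in A375 only 1 of the 26 was higher. The mitotic list had a median of -0.09 (percentile 2.75), and 0 of its 26 genes were 2-fold lower and 10 were higher, with AURKA at -0.25, PLK1 at -0.26, ANLN at -0.38 and AURKB at -0.29. The medians of these lists in the lines lay apart, but with 1 array per group the difference between lines was not tested. Invasion, matrix and protease lists were at the low end: the invasive AXL programme of melanoma had a median of -0.47, with NUAK1 at -2.11 (-1.47 with intensities under 32 set to 32) and CCN1 at -3.56 but the ligand WNT5A at 1.49 (0.23 set so), extracellular matrix genes had -0.24, and matrix proteases and inhibitors had -0.24. Endoplasmic reticulum chaperones had a median of -0.32, with 0 genes 2-fold lower. The corresponding A375 medians of these 4 lists were -0.04, 0.01, -0.06 and 0.01. Cell cycle inhibitors and D cyclins had a median of 0.30 in SK-MEL-28 and -0.16 in A375, Wnt pathway genes 0.22 and 0.06, and pluripotency factors, with 5 genes measured, 0.30 and 0.18.

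Whether the lines responded alike was asked across genes. ASNS, AMMECR1, SESN3, EGR3 and CHAC1 led the genes that were higher in both lines, followed by ATXN1, ISM1, WDR37, SESN2 and CTH. TMEM255A, ANKRD1, ZDHHC20, GSPT1 and the pentraxin PTX3 led those that were lower in both, followed by OCRL, SELENOF, the receptor IL7R, PNMA2 and EFEMP1. ISM1 was higher by 1.60 and 1.59, ATXN1 by 2.57 and 1.61, OCRL differed by -2.02 and -2.00, and IL7R by -2.07 and -1.95. WDR37 was higher by 1.54 and 1.42 on its highest probe set, but only 1 of its 2 probe sets had that sign in A375, GSPT1 had 3 of 4 probe sets with its sign in each line, and ATXN1 had 3 of 4 in SK-MEL-28. With intensities under 32 set to 32, the A375 differences of ISM1, PNMA2 and TMEM255A became 0, -0.26 and -1.16, and the SK-MEL-28 differences of ANKRD1, PTX3, EFEMP1 and IL7R became -0.25, -0.61, -0.77 and -1.37, so the sizes given for these genes rest on values near the low end of the scale. In total 43 genes were at least 2-fold higher in both lines, against 4.17 for independent lists of these sizes, and 159 were at least 2-fold lower in both, against 14.8. Only 6 genes passed the size rule in opposite ways, against 16.8. Independent lists take no account of genes with a large spread in both lines: simulated arrays with no changed gene gave 35 higher in both, 35 lower in both and 59 opposite. The simulated arrays had the same spread in both lines and no side favoured, and gave 59 opposite genes where these arrays had 6. They therefore do not describe these arrays, and the size of the excess on either side cannot be read from them. Across genes, which are not independent replicates, the differences of the lines had a Pearson r of 0.441 and a Spearman rho of 0.413, and 64.0% had the same sign. The slope of the SK-MEL-28 differences on those of A375 was 0.286.

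**Figure D2:**
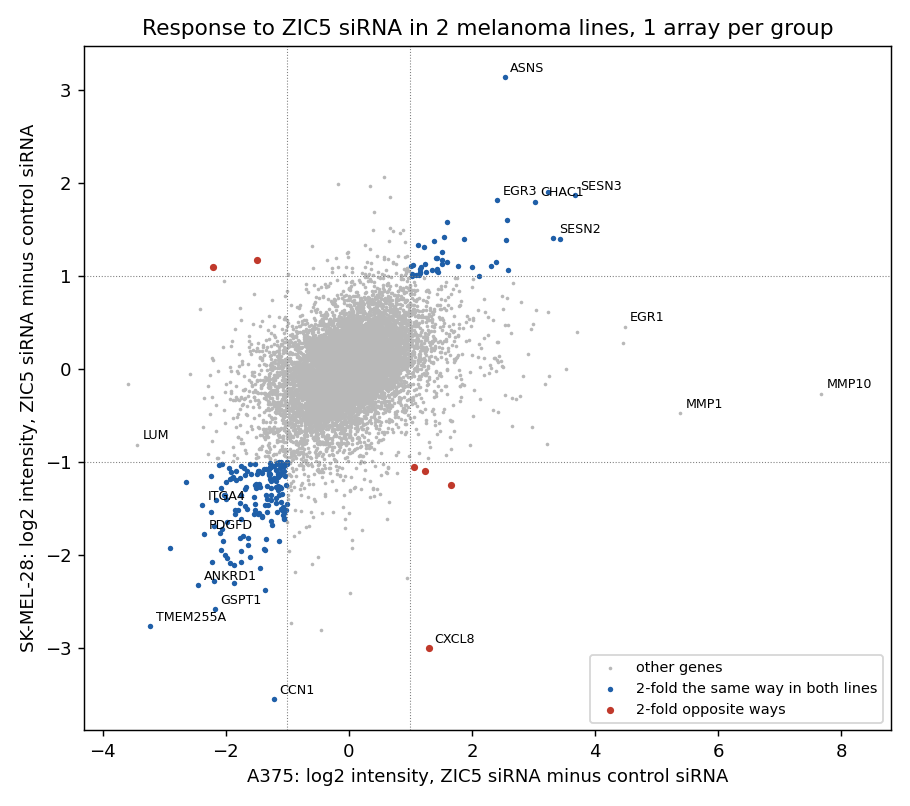
Log2 intensity with ZIC5 siRNA minus control siRNA for each of 13794 genes, A375 on the horizontal axis and SK-MEL-28 on the vertical axis, with dotted lines at the 2-fold rule (-1 and 1). Blue points are genes at least 2-fold different the same way in both lines (43 higher, 159 lower), red points the 6 that differ by 2-fold in opposite ways; XIST and Y-linked genes are not drawn.

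The siRNA effect over both lines was then fitted with limma, with the line as a block, so that the lines are the only replication. Many genes, PDGFD among them, tied at the lowest limma adjusted p of 0.268. The leading 10 higher and 10 lower genes were therefore taken in order of unadjusted p. Those higher included ASNS (mean difference 2.84, SE 0.22), ATF4 (1.05, SE 0.10), the glycyl-tRNA synthetase GARS1 (1.10, SE 0.11) and EGR3 (2.11, SE 0.23). Those lower included ANKRD1 (-2.39, SE 0.14), TMEM255A (-3.00, SE 0.19), GSPT1 (-2.38, SE 0.18) and PTX3 (-2.15, SE 0.17). Each of these had the same sign in both lines. MLC1, CADPS, RNF128, TRIB3, ISM1 and WDR37 were also among the 10 higher, and PNMA2, C1QBP, SELENOF, ZDHHC20, PPP1R9A and PHB2 among the 10 lower. With intensities under 32 set to 32, the A375 differences of MLC1 and CADPS became 0.65 and 0.33 and the SK-MEL-28 difference of PPP1R9A became -0.61, and those of ISM1, PNMA2, TMEM255A, ANKRD1 and PTX3 shrank as given above. At a Benjamini-Hochberg adjusted p under 0.05 the fit called 0 genes, the lowest adjusted p being 0.268. At an unadjusted p under 0.05 it gave 1824 genes, 815 higher and 1009 lower, against 690 expected with no effect. On simulated arrays with 200 changed genes among 13794, the same step called 0% of genes changed by 2 log2 units and 90.5% of those changed by 3 log2 units.

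Adjusted over each list alone, 11 of 40 lists held at least 1 call. On simulated arrays with no changed gene, 4% of unchanged lists of 18 genes held a call. Those simulated genes varied independently, while 1824 of 13794 genes on the real arrays had a limma unadjusted p under 0.05. The 4% is therefore not the rate for lists of arbitrary real genes, and the 11 lists cannot be weighed against it. The 40 lists also differ in size and share genes. The ATF4 stress and amino acid list held the most calls: 15 of its 18 genes passed, all higher, and the lowest limma adjusted p over the list alone was 0.00486. Called or not, 18 were higher in A375 and 17 in SK-MEL-28, and 7 were at least 2-fold higher in both lines. ASNS, the transcription factor ATF4 itself, the mTORC1 inhibitor DDIT4 and the pseudokinase TRIB3 rose in both lines, as did the serine synthesis enzymes PHGDH, PSAT1 and PSPH and the cystine transporter SLC7A11. CEBPB, SHMT2 and VLDLR did not pass, with differences of 0.51 and -0.02, 0.18 and 0.57, and 2.48 and 0.09. In the MAPK output list, made of genes switched on by ERK signalling and its feedback inhibitors, 7 of 19 genes passed, all higher: PHLDA1 (1.57 and 0.89), SPRY4 (1.35 and 1.07), DUSP6 (1.28 and 0.85), SPRED2, IER3, SPRED1 and DUSP4. In SK-MEL-28, 5 of 6 PHLDA1 and 2 of 3 DUSP4 probe sets were also higher. Called or not, 14 of the 19 genes were higher in A375 and 13 in SK-MEL-28. The median of that list was 0.55 in A375 (percentile 99.98) and 0.45 in SK-MEL-28 (percentile 100). The p53 target list was the third with a median outside the central 95% of random lists on the high side in both lines, at 0.26 in SK-MEL-28 (percentile 99.65), but 0 of its 19 genes passed over the list alone. Its members CDKN1A and SESN2 had an adjusted p of 0.0553 and 0.0806 there but 0.0187 over the cell cycle inhibitor list and 0.0185 over the ATF4 list, so these calls depend on the list used.

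Cell cycle inhibitors and cell adhesion genes gave further calls over the list alone, and rose or fell below marks members that passed. The CDK inhibitors CDKN1A (1.15 in A375 and 1.03 in SK-MEL-28) and CDKN1B (mean 1.02, SE 0.15) rose, while the pocket protein RBL2 (-1.06 and -0.72) and cyclin CCND3 (-0.91 and -0.65) fell. Of 15 integrin genes, 5 passed. ITGA4 (-2.38 and -1.47), ITGB5 (-1.09 and -1.35), ITGA6 (mean -1.18, SE 0.17) and ITGB3 (-1.08 and -0.83) were lower, while ITGA2 (1.44 and 0.69) was higher. Called or not, 5 of the 15 were higher in each line. ITGB3 is outside the rule for named genes and was added after its values were seen. The integrin list median was -0.19 in A375 and -0.15 in SK-MEL-28. Among 14 focal adhesion genes the actin linker VCL fell (-1.33 and -1.26), with list medians of 0.01 and -0.08. Among 22 extracellular matrix genes the collagen COL12A1 fell (-1.33 and -1.54), with that sign in 2 of its 3 probe sets in A375. Among 20 matrix proteases and inhibitors MMP8 (-1.41 and -1.60) and ADAM10 (-0.77 and -0.81) fell and MMP16 (1.17 and 1.10) rose. The targets of the Hippo pathway coactivators YAP and TAZ had the only list median below the central 95% of random lists in both lines, -0.36 (percentile 1.06) and -0.58 (percentile 0). ANKRD1 fell over that list alone, with the limit on its SK-MEL-28 value given above, while CCN1 (-1.22 and -3.56), AMOTL2 (-0.61 and -1.54) and FJX1 (-1.02 and -0.78, the latter -0.45 with intensities under 32 set to 32) did not pass. RPL18 (-1.04 and -1.03), lower in both lines, was the only ribosomal protein gene of 12 to pass, with list medians of 0.04 and 0.07. Of 9 heat shock genes, HSPD1 (-0.52 and -0.85) fell and DNAJB1 (0.75 and 0.59) rose, with medians of 0.02 and -0.11. In SK-MEL-28, 2 of 3 RPL18 and 3 of 4 HSPD1 probe sets had the sign given.

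Melanoma identity lists held no call over the list alone. Melanocyte pigmentation genes had a median of 0.07 in A375 and -0.01 in SK-MEL-28, although OCA2 was higher by 2.42 in A375. Some members passed the level minimum only through SK-MEL-28. In A375 the intensities were 13.9 and 17.0 for MLANA, 7.5 and 8.1 for TYRP1 and 4.8 and 3.7 for TRPM1. Others were higher there, such as GPNMB at 586 and 1215. The A375 median therefore rests in part on values near background. Neural crest and undifferentiated melanoma markers had medians of 0.06 and -0.13, with SNAI2 at 1.83 (1.26 with intensities under 32 set to 32) and L1CAM at -1.79 in A375, and NGFR at -0.85 and -0.96. Epithelial adhesion genes had medians of -0.03 and 0.00, with KRT7 at -2.12 in A375, on 1 of its 2 probe sets only, and CLDN1 at -2.03 in SK-MEL-28, and mesenchymal markers had 0.05 and -0.12, with TWIST2 at -2.35 in A375 (-1.99 with intensities under 32 set to 32). The 2 ZIC genes at the level minimum had medians of -0.71 and -0.03. Medians were -0.34 and -0.06 for the Hedgehog and GLI pathway, 0.26 and 0.00 for JAK-STAT3 components and targets, where OSMR differed by 0.06 and -1.92, and 0.00 and -0.01 for receptor tyrosine kinases, where AXL differed by -1.24 and -0.54, with a second probe set at 1.13 in SK-MEL-28. TGF-beta and BMP targets had medians of 0.08 and -0.08, with ID2 at 1.33 and 0.57.

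Further lists without a call had medians inside the central 95% of random lists in both lines. Interferon-stimulated genes had -0.06 in A375 and -0.05 in SK-MEL-28, antigen presentation genes 0.09 and 0.02, and RNA interference machinery 0.27 and 0.07, with AGO3 at 1.52 in A375, a sign that 3 of its 4 probe sets had. Hypoxia and glycolysis genes had -0.18 and 0.07, and oxidative phosphorylation genes -0.06 and 0.06. Markers of cell types other than melanoma had medians of -0.18 and -0.17 for keratinocytes, -0.07 and -0.05 for fibroblasts and -0.15 and -0.04 for leukocytes. For the lists that stood apart in A375, the SK-MEL-28 medians not yet given were 0.07 for lysosome and autophagy, -0.07 for NF-kB targets, 0.04 for apoptosis regulators, 0.10 for DNA repair and 0.07 for cholesterol synthesis. In A375, 6 lists lay above and 5 below the central 95% of random lists, and in SK-MEL-28, 7 above and 6 below. For lists of randomly drawn genes 2 of 40 would lie outside in each line. Members of a list may vary together and some genes are in several lists, so that number is no test.

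**Figure D3:**
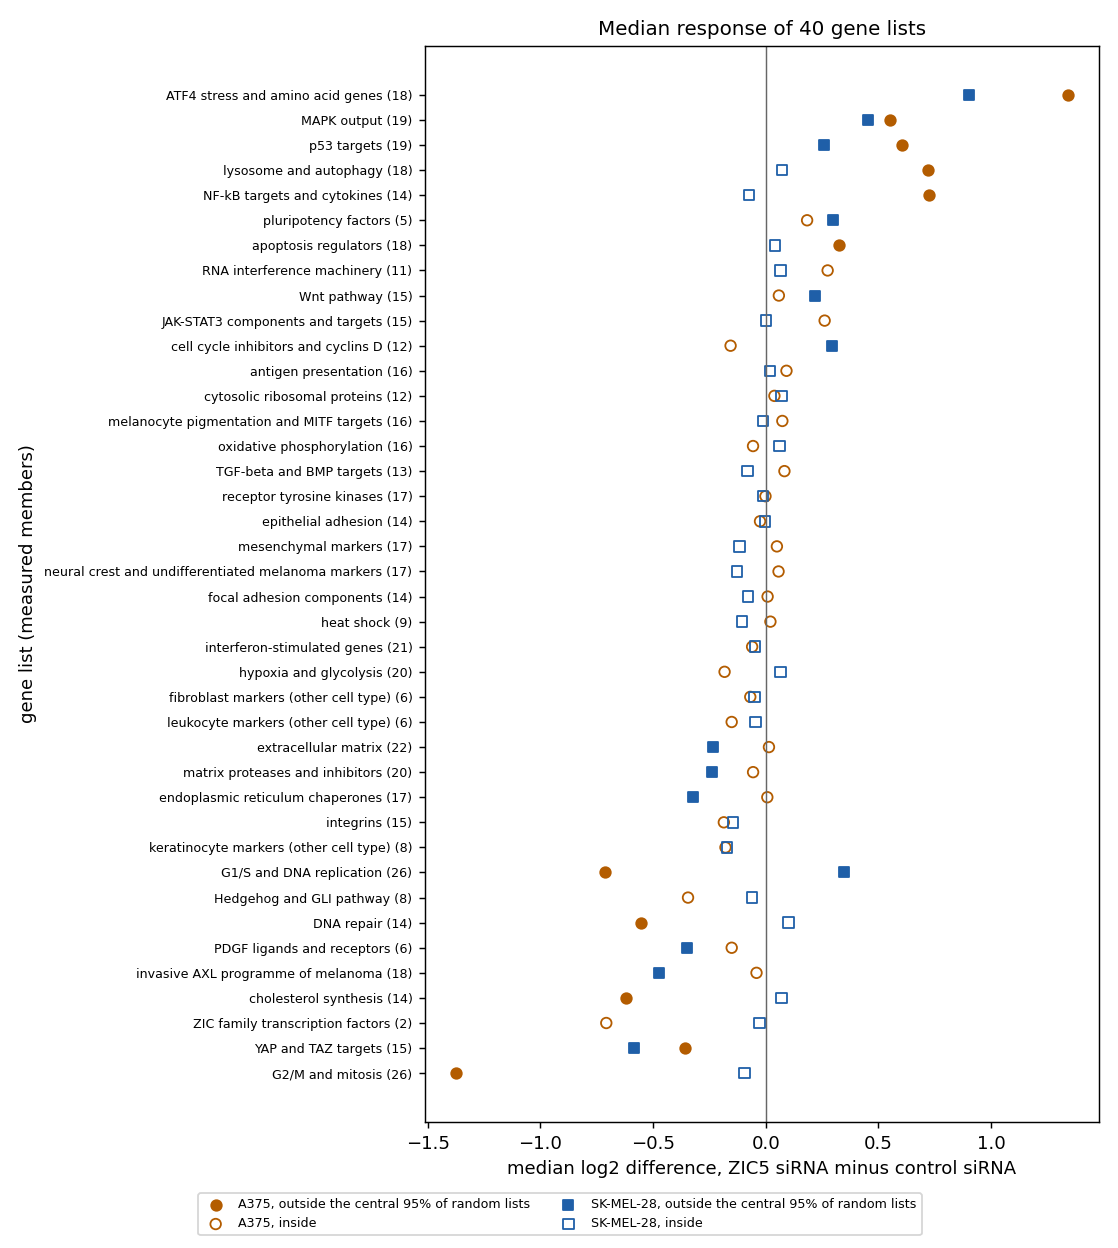
Median log2 difference (ZIC5 siRNA minus control siRNA) of the measured members of 40 gene lists, orange circles for A375 and blue squares for SK-MEL-28, filled where the median lies outside the central 95% of 10000 random lists matched on level. The ATF4 list is highest in both lines (1.34 and 0.90), and the mitotic list is lowest in A375 (-1.38) but near 0 in SK-MEL-28 (-0.09).

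The cell line difference, from the same fit with the transfection as a block, gives the scale of expression differences between these melanomas. Among the genes with the greatest difference toward SK-MEL-28, the melanocyte antigen MLANA differed by -10.17 (A375 minus SK-MEL-28, SE 0.19), the melanosome protein PMEL by -8.25 (SE 0.17) and the melanin enzyme TYRP1 by -7.23 (SE 0.18), each with a limma adjusted p of 0.00225. GPM6B, PLA1A, LXN, PEG10, PMP2, the melanocyte channel TRPM1 and RGS1 were the other leading genes on that side. With intensities under 32 set to 32, the differences of MLANA and TYRP1 became -9.11 and -5.20, so these 2 are set in part by background in A375. That of PMEL stayed the same, but its A375 intensities of 32.4 and 35.9 lay just over 32 and under the array medians. Background may therefore enter the PMEL difference too. A375 had higher levels of the RNA LINC01419 (8.46, SE 0.39), the adhesion protein AMIGO2 (8.22, SE 0.21), the branched-chain amino acid enzyme BCAT1 (7.86, SE 0.20), the activin subunit INHBA (7.15, SE 0.42) and the calcium-binding protein S100A4 (7.05, SE 0.20). SYTL5, GTSF1, IL13RA2, LINC01029 and TRHDE completed the leading genes. With intensities under 32 set to 32, the differences of LINC01419, AMIGO2 and BCAT1 became 5.59, 7.14 and 6.16, while those of INHBA and S100A4 stayed the same. The SK-MEL-28 intensities of INHBA (40.4 and 36.8) and S100A4 (44.4 and 39.5) were near the array medians. The order of these genes is therefore not well measured. The fit called 1963 genes higher in A375 and 1853 higher in SK-MEL-28 at a limma adjusted p under 0.05. Log2 values correlated over probe sets at r = 0.976 between the A375 arrays and 0.990 between the SK-MEL-28 arrays, against 0.932 between the control arrays of the lines. As 1 array per group was measured, these p-values measure only the spread between these arrays.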

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

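The results in this part come from fixed size rules, and no test was run in it. In 6 genes the lines differed from their controls in opposite ways by at least 2-fold, which is what singled them out, and the difference between the lines was not tested because each group held 1 array. The chemokine CXCL8 was higher by 1.31 in A375 and differed by -3.01 in SK-MEL-28, with the same signs in both of its probe sets. The FGF signalling inhibitor IL17RD had 1.24 in A375 and -1.10 in SK-MEL-28. The RNA LINC02249 had -2.20 in A375 and 1.09 in SK-MEL-28. The phosphodiesterase PDE2A had 1.05 in A375 and -1.06 in SK-MEL-28. The phospholipase family gene PLCXD2 had 1.65 in A375 and -1.25 in SK-MEL-28. The phosphatase gene PXYLP1 had -1.49 in A375 and 1.17 in SK-MEL-28. With intensities under 32 set to 32, the A375 difference of LINC02249 became -0.73 and the SK-MEL-28 differences of PDE2A and PLCXD2 became -0.63 and 0. Chance overlap of independent lists would give 16.8 such genes, and simulated arrays with no changed gene gave 59.

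Probe sets with no gene name here, which enter no comparison of the report, also passed the size rule in both lines. Of 3820 such probe sets at the level minimum, 19 were at least 2-fold higher in both lines, against 2.89 for independent lists, and 16 were at least 2-fold lower in both, against 0.94, numbers that take no account of probe sets with a large spread in both lines.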

How the results depend on the processing

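The checks of list members over the list alone, of 2-fold members of the ATF4 and mitotic lists and of line differences with values under 5 set to 5 were added after the data were seen; the others were planned. With the 1.5-fold rule the A375 counts became 1671 higher and 1786 lower, the SK-MEL-28 counts 580 and 884, genes past the rule the same way in both lines 753 and opposite ways 64, and 14 ATF4 genes passed in SK-MEL-28. With the 3-fold rule they became 154 and 154, 12 and 59, 33 and 0, with 8 ATF4 genes in A375, 2 in SK-MEL-28 and 7 mitotic genes lower in A375. These follow from the rule itself. With the mean of all probe sets they became 340 and 442, 48 and 157, 110 and 1, and WDR37 turned to -0.31 in A375, since that mean also takes in a probe set under the level minimum (-1.75) beside those of -0.71 and 1.54. The minimum of 7, which leaves fewer genes, gave 444 lower in A375, 188 lower in SK-MEL-28 and 2 opposite. With values under 5 set to 5, 3 genes were opposite and the ZIC5 difference became 0 in both lines, since its 4 intensities lie under that value: signal over background limits what these arrays show of ZIC5. Without the block, the line difference gave 1302 genes higher in A375, and calls over the list alone went from 41 to 0, ATF4 members included (15 to 0), as the difference between lines then enters the spread. Calls over the list alone were 67 at an adjusted p under 0.1 and 26 with an added 2-fold minimum. The remaining counts stayed within 1.5 times, the correlation of the lines ran from 0.390 to 0.498, and the limma siRNA effect called 0 genes in every setting run. Of the list medians, 480 alternative values moved by less than the SD of random lists, 46 by more, and 0 of those outside the central 95% changed sign. Of the named-gene values, 1828 moved by less than the median SD between probe sets, 227 by more, and 1 of those at least 2-fold changed sign. Changes of sign among values under 2-fold were not counted. No line could be left out, because no residual degree of freedom would remain.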

Other observations

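The tests chosen only after the result was seen were those of level trend and of off-target silencing for the shared response, of knockdown efficiency, of SK-MEL-28 as a smaller copy of A375 for mitotic genes, and of exchanged labels; the 4 lists of the next paragraphs were also added after the data were seen. Among enzymes that charge tRNAs in the cytosol, the median over 17 aminoacyl-tRNA synthetases was 0.47 in A375 (percentile 99.95) and 0.30 in SK-MEL-28 (percentile 99.98), with 12 and 13 of the 17 higher. GARS1 (1.16 and 1.04), WARS1 (1.72 and 0.97) and CARS1 (1.11 and 0.68) passed limma adjusted over the list alone, the lowest adjusted p being 0.0103. As the list was added after the data were seen and GARS1 is also among the leading higher genes of the limma fit, these calls are not independent evidence. The 15 mitochondrial synthetases measured had medians of -0.17 and -0.09. Cytosolic synthetase genes are textbook targets of ATF4, and the hypothesis that they form part of the shared ATF4 response predicted a higher median for them than for the mitochondrial enzymes. The medians differed by 0.63 in A375 and 0.39 in SK-MEL-28, 0.51 on average, which is consistent with that hypothesis.

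Immediate early genes, the transcription factors and phosphatases induced within minutes of a stimulus, had a median of 0.88 over 20 genes in A375, above all random lists, and 0.11 in SK-MEL-28 (percentile 89.0). FOS was higher by 2.45 in A375 against 0.14 in SK-MEL-28 and DUSP1 by 1.27, on 1 of its 2 probe sets, against -0.04, while EGR3 (2.41 and 1.82) passed limma adjusted over the list alone (adjusted p 0.0180). EGR3 too is among the leading higher genes of the limma fit, so its call over this added list is not independent evidence. IER3, which passed over the MAPK output list, had an adjusted p of 0.0537 over this one. Proteasome subunits had medians of -0.06 and 0.05 over 27 genes, and PSMA7 (-1.03 and -1.02) was the 1 member that passed over that list alone (adjusted p 0.0201).

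The shared response of the lines, a correlation of 0.441 across genes, was weighed against a trend of the differences on signal level and against silencing of other transcripts by the ZIC5 siRNA. After the trend was removed by loess the correlation was 0.441 (95% bootstrap interval 0.419 to 0.462), which argues against that trend. Off-target silencing would raise sharing among lower genes above that among higher ones, and over the numbers for independent lists it was 10.8 times for lower and 10.3 times for higher genes, a ratio of 1.04 (95% bootstrap interval 0.813 to 1.38). That interval includes 1, so the ratio does not decide the question. Simulated arrays with no changed gene gave 35 each way by their design and do not hold the list sizes of the lines. The observed 159 lower and 43 higher can therefore not be weighed against them here. Without the siRNA sequence, not used here, off-target silencing cannot be told apart from an effect of ZIC5. With the control and ZIC5 labels exchanged in 1 line, the other way to part both lines, the limma fit gave 115 genes at an unadjusted p under 0.05 against 1824, and 1 of the 2 splits reached the real count, too few splits for a share under 0.05. That exchange swaps the shared effect with the disagreement of the lines, so the lower count follows from their positive correlation and is no separate check.

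The A375 response was larger than that of SK-MEL-28, with 1234 against 399 genes at least 2-fold different, and probe-set noise and knockdown efficiency were weighed as reasons. The covariance of 2 probe sets of the same gene, which independent probe-set noise does not raise, was 0.224 in A375 and 0.103 in SK-MEL-28 over 6635 genes, a ratio of 2.17 (95% bootstrap interval 1.97 to 2.38), which argues against such noise as the whole reason. The ZIC5 difference in SK-MEL-28 minus that in A375 was -0.22, but the probe set was near the low end of the scale, so a less complete knockdown in SK-MEL-28 stays open. A difference between the samples, such as transfection stress or density, and a biological difference between the lines also stay open and were not tested.

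The mitotic list median was -1.38 in A375 and -0.09 in SK-MEL-28, a difference between lines that was not tested. A trend on signal level was argued against by the loess-corrected A375 median of -1.43. If the SK-MEL-28 response were a smaller copy of the A375 response, its mitotic median would lie between -0.49 and -0.23, and it was -0.093, outside that range. The range comes from random lists and 1 fixed slope, and it may be too narrow for genes that vary together. The growth state of the cells at harvest and a biological difference between the lines stay open and were not tested.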
